A study of Canis lupus familiaris with 8 samples.

How the data were processed

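Bulk RNA sequencing compared retina from eyes prepared in 2 ways in the dog (Canis lupus familiaris, male wild-type Beagles, 31 weeks of age). Per the labels' protocols, right eyecups were divided into 4 quadrants and embedded unfixed in a freezing medium (fresh-frozen, 4 libraries). Left eyecups were kept in 4% paraformaldehyde (PFA) for 3 h and in 2% PFA for 24 h at 4 °C, passed through 15% and 30% sucrose for 24 h each, and embedded in the same medium (PFA-fixed, 4 libraries). RNA of fresh-frozen tissue was extracted with a column kit for small samples, and RNA of fixed tissue with a kit for paraffin-embedded tissue that included 18 h of proteinase K at 56 °C and a further DNase digestion. Libraries of both groups were made with one stranded total RNA kit for low input. The preparation, the side of the eye and the extraction kit therefore change together. The series' title speaks of laser capture, and the labels do not say whether these 8 libraries were captured from sections.

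Per the submitters' processing notes, kallisto 0.48.0, edgeR and limma were used by the authors, with no role or order given. kallisto is a pseudo-aligner that assigns reads to transcripts. The transcript reference, the strand setting and the filter are not given in the sources used here. The deposited table holds log2 CPM, the log2 of counts scaled to the size of each library, for 12824 genes named by symbol, with no symbol used more than once, and 8 columns of values. Every gene exceeded 1 CPM in at least 4 libraries. All libraries shared one lowest value of -3.12 log2 CPM (0.115 CPM). The sums of the linear values ran from 947376 to 1058310, as after a scaling between libraries. No mitochondrially encoded mRNA, small structural RNA or listed long noncoding RNA was among the genes. Of the symbols, 12495 matched a gene table of the assembly UU_Cfam_GSD_1.0, 12479 of them protein-coding, and 329 did not match. That table was used only for names and for which genes neighbour each other.

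Depth was estimated from the low values. Above the shared lowest value, the values of a library lay on a comb whose spacing is what 1 read is worth. This gave effective depths of 21670000, 21800000, 22210000 and 22760000 reads for fresh-frozen replicates 1 to 4, and of 12330000, 11040000, 15410000 and 12430000 for PFA-fixed replicates 1 to 4. The spacing was searched between 0.03 and 0.15 CPM. Between 60.4% and 67.3% of values of up to 20 reads were whole multiples within a tolerance of 0.1 of a read, where chance gives 20%, so the table was not turned back into reads and no count test was run. At the mean depth, the lowest value equals 2.01 reads. A change of a gene near that value is therefore understated by the added reads.

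The main test was limma 3.58.1 with an intensity trend in R 4.3.3, on the deposited log2 values, with the group as the only term, no further filter and Benjamini-Hochberg adjustment over all 12824 genes at a threshold of 0.05. The planned count model was not used because the table holds log2 CPM. Changes are PFA-fixed minus fresh-frozen, so that a positive value is higher after fixation. In a simulation of the comparison over 12824 genes, the step recovered 66% of 50 genes changed 1.5-fold and 88% of 50 changed 2-fold. It recovered 96% of 50 changed 4-fold and 100% of 50 changed 8-fold, and called 6 of 12624 unchanged genes. Far fewer genes were changed there than the 68.7% called in the data, and noise was drawn independently for each gene. These rates therefore check the step and do not carry over to the data.

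Lists of 33 cell types and gene groups were fixed before the data were examined, as was the rule for the genes named. The rule takes genes with an adjusted p under 0.05, a change of at least 1 on the log2 scale, a mean of at least 3 log2 CPM in the higher group and no overlap between the groups, and among these names the 12 largest rises and the 12 largest falls. It adds the 10 most abundant genes of fresh-frozen retina and, for each list, the 2 members with the highest mean level and the 2 called members with the largest change. Some genes that the rule takes, and 1 test that used such a gene, are not reported here. Lists of at least 5 measured members (27) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Genes detected (at least 1 CPM), shares of the library and the spread between replicates were compared by exact two-sided permutation over 70 assignments (35 splits for the spread), whose smallest p is 0.0286. The test planned for the slope against the mean fresh-frozen level is left out, because fixed libraries are set against the other group there. Correlations between libraries are across genes, which are not independent replicates, and carry no p.

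Alternatives were leaving out each library, the replicate number as a block, quantile normalization, centring each library on its median, a minimum mean of 3 log2 CPM, limma without trend, and a test against a 1.5-fold change. Added after seeing the data were log2(CPM + 1), library quality weights, and centring each library on its rod list. The rod centring was first run on the median of the list, and the version on its mean was written after that result had been seen; both are reported. Genes that share sequence with near-identical copies, among them ribosomal protein genes, histone genes and EEF1A1, and genes that overlap others, are uncertain, because the division of shared reads rests on the reference the authors used. Transcript length and GC content were not used here, and gene coordinates only for the order of genes. Figures were drawn with matplotlib 3.10.9.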

Results

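Retina of fresh-frozen and of PFA-fixed dog eyecups was profiled by total RNA sequencing, with 4 libraries for each preparation. PFA is a crosslinking fixative used for histology. The effective depth was 22110000 ± 490000 reads in fresh-frozen and 12800000 ± 1850000 in PFA-fixed libraries (SD, n = 4 each), a 1.73-fold difference (exact permutation p = 0.0286, two-sided). The question was how far the measured transcriptome of retina depends on the preparation. Fixation, the side of the eye and the extraction kit changed together, so each difference belongs to the whole preparation. The p-values measure the spread between these 8 libraries. The labels call the 4 libraries of a group biological replicates and do not say which came from one dog.

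Of 27 tested gene lists, those of fibrous, pigmented and vascular tissue had the lowest median changes on the log2 scale, between -7.02 and -2.64 in PFA-fixed against fresh-frozen retina, whereas the median of the rod list was 0.22. Type I collagen COL1A1 and the melanin enzyme DCT fell by 9.27 and 7.77, and the largest rise was 5.89, for CCNDBP1. Of 12824 genes, 8804 differed with limma (68.7%), of which 4353 rose and 4451 fell in PFA-fixed retina. Of these, 1356 rose and 1756 fell at least 2-fold, 214 rose and 749 fell at least 4-fold, and 14 rose and 173 fell at least 16-fold. The groups did not overlap in 8061 genes (62.9%, where chance gives 2.86%). Most changes were small, since 75.6% of genes lay within 2-fold and the median change was -0.02 with a median SE of 0.115. A test against a minimum change of 1.5-fold called 3343 genes, 1530 higher and 1813 lower. Rising genes made up 49.4% of calls with the deposited scaling, and 31.2% (2685 higher, 5912 lower) when each library was centred on the mean of its rod list, which gave all genes a median change of -0.27. Centring on the median of the rod list gave a median change of -0.67 and 12.4% rising (1138 higher, 8074 lower), with 415 called genes of opposite sign. That centring overshot the rod genes themselves, whose median change was then -0.43. Rises of at least 2-fold numbered 888 with the rod list mean and 424 with its median. Falls of at least 2-fold numbered 4180 with the median. The counts of small and of larger rises therefore depend on the scaling.

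**Figure D1:**
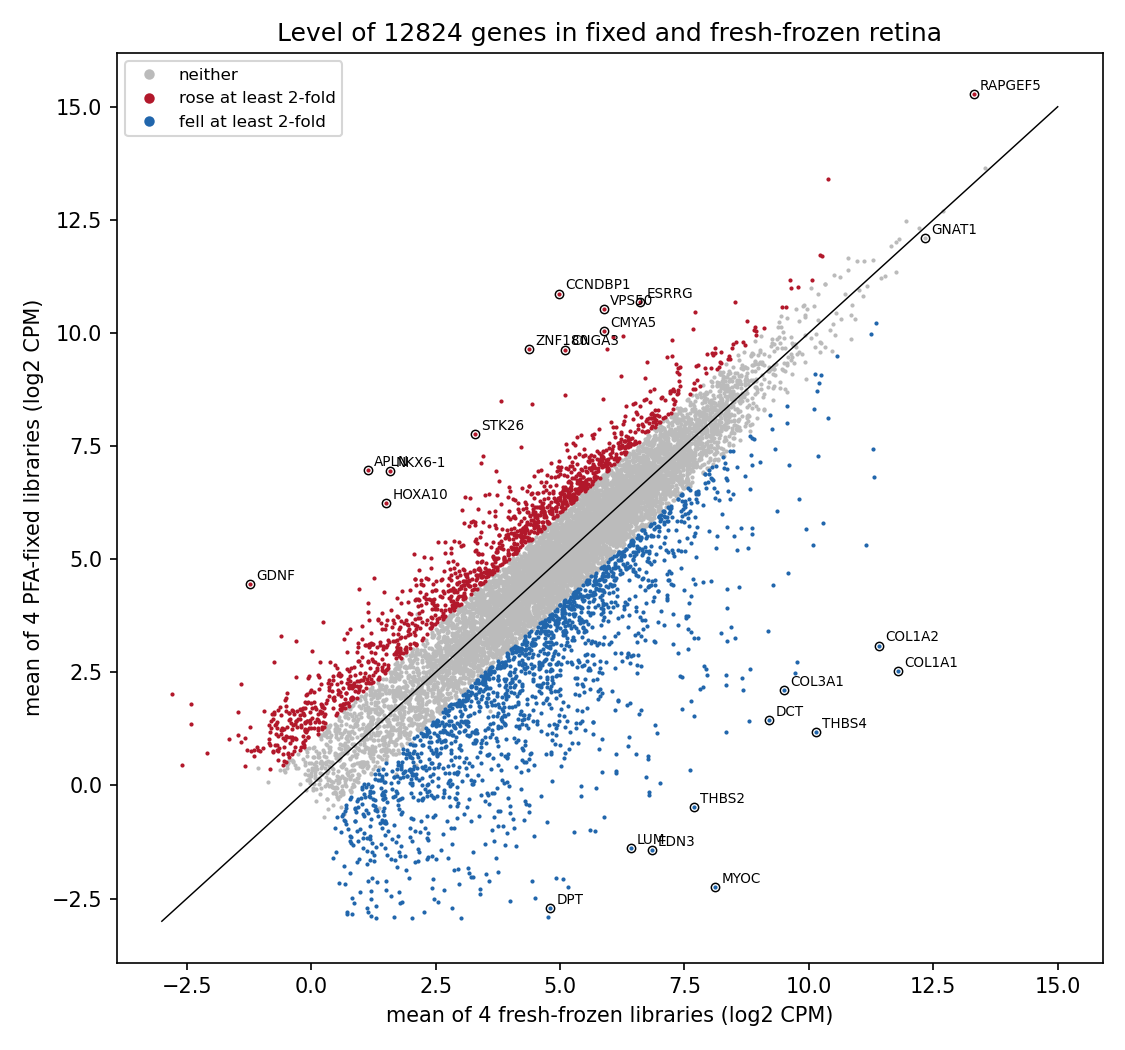
Mean level of each of 12824 genes in 4 fresh-frozen libraries (x axis, log2 CPM) and in 4 PFA-fixed libraries (y axis, log2 CPM), with the line of equal levels. Red points rose and blue points fell at least 2-fold with a limma adjusted p under 0.05, grey points did neither, and circles mark named genes. The 1756 fallen genes reach much further from the line than the 1356 risen ones.

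The largest falls were led by MYOC, the secreted glycoprotein myocilin, which fell by 10.37 ± 0.51 (SE) on the log2 scale, from 8.12 ± 0.77 log2 CPM to -2.25 ± 1.13 (SD, n = 4 each; limma adjusted p = 1.07e-08), with 2 fixed libraries at the lowest value of the table. Fibrillar collagen genes were among them. COL1A1 went from 11.80 ± 0.36 to 2.52 ± 0.28 log2 CPM, COL1A2 from 11.42 ± 0.23 to 3.09 ± 0.16 and COL3A1 from 9.50 ± 0.48 to 2.10 ± 0.61 (SD, n = 4 each), with limma adjusted p-values of 7.14e-12, 7.87e-13 and 1.86e-09. Other matrix genes among the 12 largest falls were THBS4 (-8.97), THBS2 (-8.17), LUM (-7.81) and DPT (-7.52), which encode 2 thrombospondins, lumican and dermatopontin. The peptide endothelin 3 (EDN3) fell by 8.26 and DCT by 7.77. DPT, like MYOC, stood at the lowest value in 2 fixed libraries, so the size of these changes depends on the reads added before the log.

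The largest rises had no list in common. CCNDBP1, a cyclin D-binding protein, rose by 5.89 ± 0.10 (SE), from 4.98 ± 0.13 to 10.87 ± 0.20 log2 CPM (SD, n = 4 each; limma adjusted p = 4.63e-12). The peptide hormone apelin (APLN) rose by 5.83, from 1.14 ± 0.11 to 6.97 ± 0.19 log2 CPM, and the growth factor GDNF by 5.68, from -1.22 ± 1.17 to 4.46 ± 0.34. Homeobox genes whose usual sites of expression lie outside the retina were among them, with NKX6-1 up by 5.38 and HOXA10 by 4.73. The zinc finger gene ZNF180 rose by 5.28, the tethering factor gene VPS50 by 4.65 and the kinase gene STK26 by 4.46. CNGA3, a subunit of the cone cyclic nucleotide-gated channel, rose by 4.52, from 5.11 ± 0.44 to 9.63 ± 0.20 log2 CPM. CMYA5 rose by 4.16 and the orphan nuclear receptor gene ESRRG by 4.07. The adjusted p of each of these genes with limma lay at or below 7.17e-07, and all 4 fixed libraries exceeded all 4 fresh-frozen ones.

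The 10 most abundant genes of fresh-frozen retina included genes of the rod list, and COL1A1. The G protein subunit genes GNAT1 and GNB1 differed by -0.23 (limma adjusted p = 0.0462) and 0.12 (limma adjusted p = 0.292), and the call of GNAT1 ended without any single library other than fresh-frozen replicate 1 and PFA-fixed replicate 3 (-0.23 to -0.19). The disc protein gene PRPH2 rose by 0.27 (limma adjusted p = 0.0264), a call that ended without any single library other than fresh-frozen replicate 2 and PFA-fixed replicate 4 (0.23 to 0.27). Quantile normalization turned GNB1 and PRPH2 to -0.21 and -0.026, and centring on the rod list median to -0.53 and -0.38. RAPGEF5, a guanine nucleotide exchange factor gene, rose by 1.96 from 13.31 ± 0.25 to 15.27 ± 0.09 log2 CPM (limma adjusted p = 2.61e-07). The amino acid transporter gene SLC38A4 was at 12.70 in both groups as deposited, and was called lower in fixed libraries after quantile normalization (-0.52) and with the rod list mean (-0.25) and median (-0.65). MAP1B, a neuronal cytoskeletal gene, rose by 0.52 (-0.13 with the rod list median). HSP90AA1 differed by 0.26 (limma adjusted p = 0.0812), and was called without PFA-fixed replicate 1 (0.34, limma adjusted p = 0.0328), with the replicate block (limma adjusted p = 0.0265) and with median centring (0.34, limma adjusted p = 0.0265), but called lower with the rod list median (-0.39, limma adjusted p = 0.0422).

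Lists of tissues that lie outside the neural retina fell together. All 11 measured genes of the sclera and fibroblast list fell, with a median change of -7.02 and members between -9.27 and -5.76 (camera adjusted p = 2.68e-09; adjusted p = 0.163 with an estimated correlation). The list took 1.04 ± 0.143% of the fresh-frozen and 0.00541 ± 0.00119% of the fixed library (SD, n = 4 each; exact permutation p = 0.0286, a share added after seeing the data). Of 9 melanin and melanocyte genes, 8 fell, with a median of -5.31 (camera adjusted p = 6.30e-05; adjusted p = 0.163 with an estimated correlation). The melanosome genes PMEL and TYRP1 fell by 6.29 and 6.23, while SLC45A2, a melanosomal transporter gene, was at 6.27 ± 0.07 and 6.26 ± 0.05 log2 CPM as deposited and called lower with the rod list mean (-0.26) and median (-0.66). All 11 retinal pigment epithelium genes fell, with a median of -3.50 (camera adjusted p = 1.99e-05; adjusted p = 0.163 with an estimated correlation). Their visual cycle enzymes RPE65 and LRAT fell by 4.89 and 5.27, and RGR, which Müller cells also express, fell by 0.48. The counts were the same when adjusted over the list alone.

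Vascular and immune lists fell as well. All 9 pericyte and smooth muscle genes fell, with a median of -3.58 (camera adjusted p = 1.97e-05; adjusted p = 0.163 with an estimated correlation). Among them, ACTA2 fell by 3.84, CSPG4 by 3.81, MYH11 by 2.26 and PDGFRB by 2.04. Of 11 endothelial genes, 10 fell, with a median of -2.64 (camera adjusted p = 1.97e-05; adjusted p = 0.163 with an estimated correlation). The adhesion gene PECAM1 fell by 3.26 and the tight junction gene CLDN5 by 2.98, whereas the receptor gene KDR differed by -0.16 (limma adjusted p = 0.243), and was called lower without fresh-frozen replicate 3 (-0.25, limma adjusted p = 0.0407), after quantile normalization (-0.27) and with the rod list mean (-0.41) and median (-0.80). Of 15 microglia and macrophage genes, 13 fell and none rose, with a median of -2.49 (camera adjusted p = 6.30e-05; adjusted p = 0.221 with an estimated correlation), and too few of them reached the minimum level of 3 log2 CPM to be tested with it. TMEM119 fell by 6.97, C1QC by 3.25, CSF1R by 2.78 and CD74 by 2.65. The counts adjusted over the list alone were 9, 10 and 13.

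Of 15 Müller glia genes, 9 fell and none rose, and 9 fell when adjusted over the list alone. Their median was -0.65 (camera adjusted p = 0.00316, and 0.520 with an estimated correlation). It was -0.90 and -1.29 with the rod list mean and median. The apolipoprotein gene APOE fell by 4.77 and SPP1 by 3.70, while the glutamine synthetase gene GLUL fell by 0.61 and VIM by 1.12. Whether the large falls of APOE and SPP1 come from Müller cells or from other cells was not tested. Of the 3 measured astrocyte genes, AQP1 fell by 4.44 and GFAP by 3.33 ± 1.17 (SE; limma adjusted p = 0.0245), and the call of GFAP ended without PFA-fixed replicate 2 (-2.82) or 3 (-3.05) and with limma without trend (limma adjusted p = 0.0573). Without fresh-frozen replicate 1 the change of GFAP was -2.02. The remaining astrocyte gene differed by 0.26 and was not called. Whether the fall of AQP1 comes from astrocytes or from other cells was not tested. Of 10 oligodendrocyte and myelin genes, 6 fell and 1 rose, with a median of -1.65 that did not pass (camera adjusted p = 0.0896). SOX10 fell by 5.78, ERMN by 4.31 and CNP by 1.66, and OLIG2 rose by 0.99. SOX10, ERMN, CNP and MBP were lower in every fixed library than in every fresh-frozen one. In fresh-frozen replicates 2 to 4, MAG was at 2.19 to 2.70 and MOG at 1.01 to 2.15 log2 CPM. Fixed libraries held MAG at 2.29 to 3.15 and MOG at 2.21 to 2.54. The mean of this list in fresh-frozen replicate 1 was 5.66 log2 CPM, against 3.43 to 3.52 in the other 3 fresh-frozen libraries. SOX10 did not share this high value, at 6.93 log2 CPM there and 6.76 to 7.17 in the other 3. Whether its fall comes from oligodendrocytes or from other cells was not tested.

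**Figure D2:**
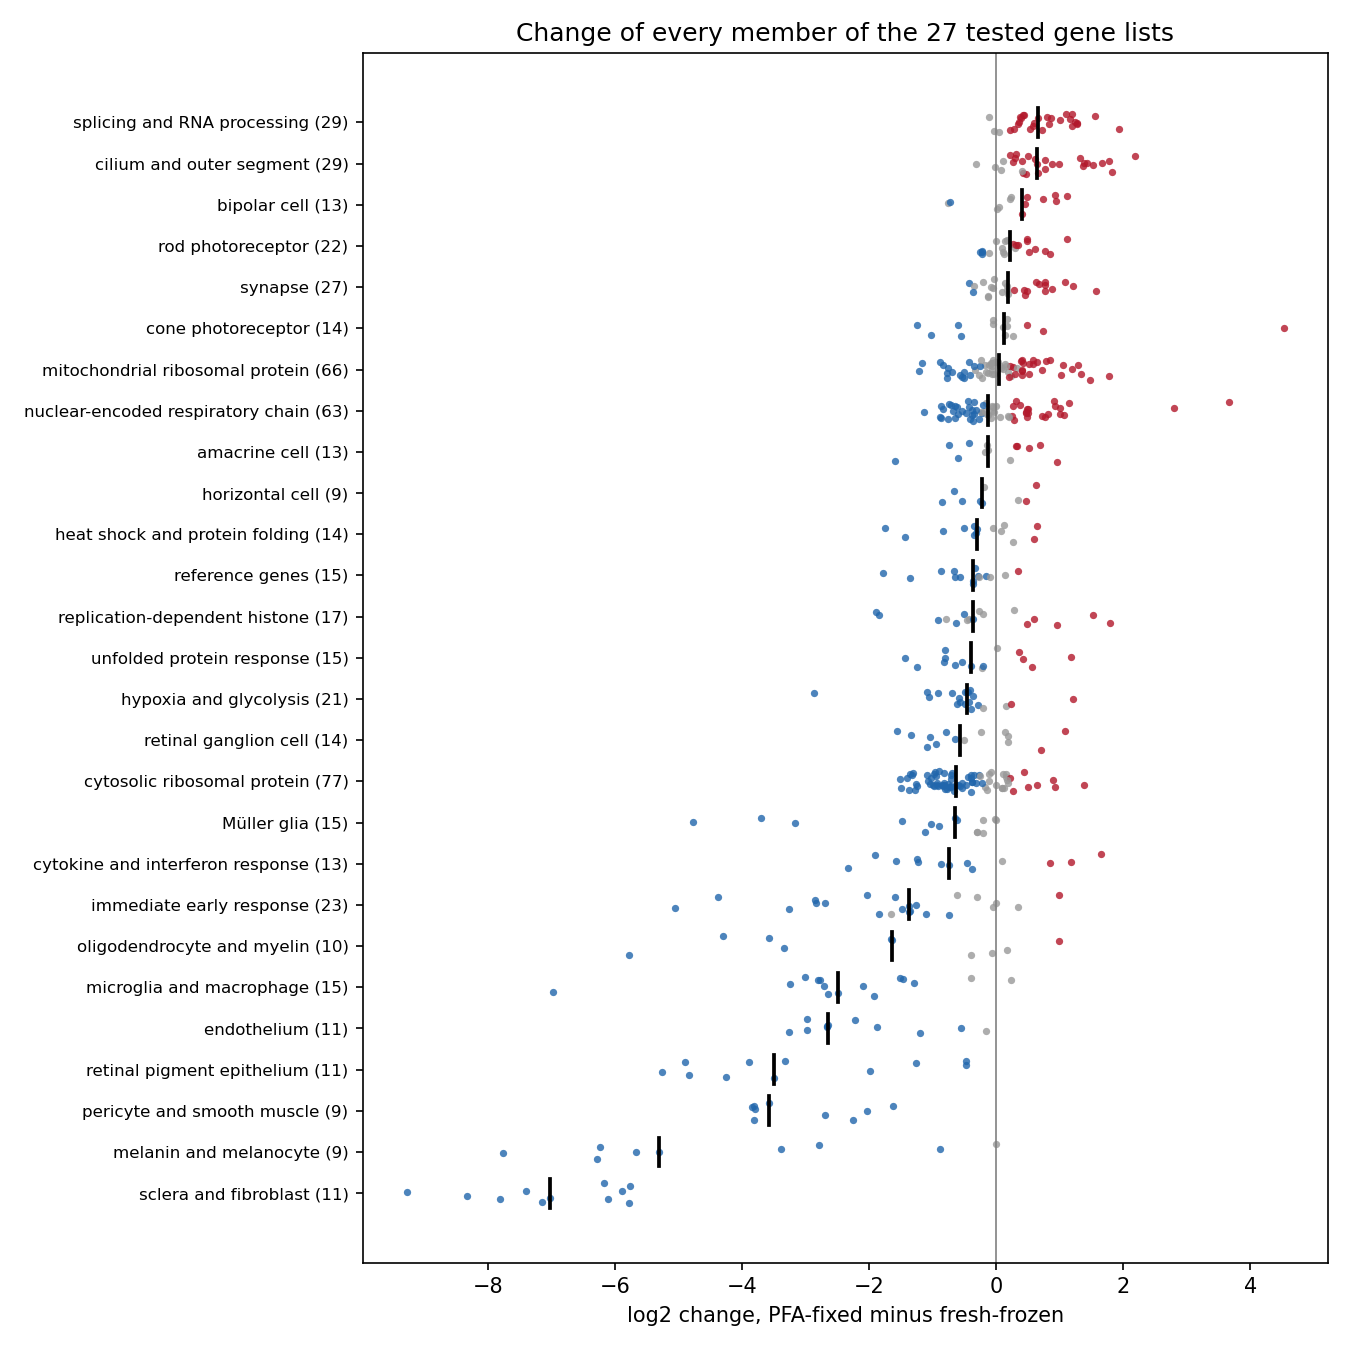
Change of each measured member (points) of the 27 tested gene lists, as log2 of PFA-fixed minus fresh-frozen (x axis), with the number of members in brackets and the list median as a black bar. Red members rose and blue members fell with a limma adjusted p under 0.05, and grey members did not pass. List medians run from -7.02 for the sclera and fibroblast list to 0.66 for the splicing and RNA processing list.

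Lists of retinal neurons had medians between -0.57 and 0.40, and camera called none of them. Of 22 rod genes, 10 rose and 4 fell, with a median of 0.22 (camera adjusted p = 0.0896). Camera called the rod list without fresh-frozen replicate 2 (median 0.28, camera adjusted p = 0.0265) or PFA-fixed replicate 4 (0.27, camera adjusted p = 0.0468). It was also called with the replicate block (camera adjusted p = 0.0466). Its median was -0.00716 after quantile normalization. The rod phosphodiesterase gene PDE6B rose by 1.11 and the channel gene CNGB1 by 0.85 (0.20 with the rod list median, where its call ended). Of 13 bipolar cell genes, 7 rose and 1 fell, with a median of 0.40 (camera adjusted p = 0.0896), 0.14 with the rod list mean and -0.25 with the rod list median. GRM6 and TRPM1, the receptor and channel of ON bipolar cells, rose by 1.11 and 0.93. Of 14 cone genes, 3 rose and 4 fell, with a median of 0.12 (camera adjusted p = 0.827), -0.13 with the rod list mean and -0.53 with the rod list median. Beside the rise of CNGA3, RXRG fell by 1.25 and KCNV2 by 1.03, and PDE6H differed by -0.05 (-0.70 and called with the rod list median). Of 9 horizontal cell genes, 2 rose and 5 fell, with a median of -0.22 (camera adjusted p = 0.827). PROX1 and TPM3 rose by 0.47 and 0.62 (-0.18 and -0.026 with the rod list median), C1QL2 fell by 0.66, and the fall of ONECUT3 (-0.85, limma adjusted p = 0.0463) ended without any single library other than fresh-frozen replicate 1 and PFA-fixed replicate 2 (-0.92 to -0.57).

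Amacrine cell genes went both ways, with 5 of 13 up, 4 down and a median of -0.14 (camera adjusted p = 0.973). PAX6 rose by 0.52 (-0.13 with the rod list median) and CHAT by 0.96 (0.70 and 0.31 with the rod list mean and median, not called in either), and TFAP2A fell by 1.59. The median and mean of this list were negative, while camera placed it upward. Of 14 retinal ganglion cell genes, 2 rose and 7 fell, with a median of -0.57 (camera adjusted p = 0.324), and of -0.76 to -0.38 without single libraries. With the rod list mean and median this median was -0.83 and -1.22. THY1 fell by 1.56, POU4F1 by 1.34 and NEFL by 0.64, and NEFM rose by 0.70 (0.44 and 0.047 with the rod list mean and median, not called in either). The call of NEFL ended without fresh-frozen replicate 3 (-0.42) or PFA-fixed replicate 2 (-0.53) or 3 (-0.54), and with limma without trend. Adjusted over the list alone, the rises and falls numbered 10 and 4 for rods, 7 and 1 for bipolar cells, 3 and 3 for cones, 2 and 5 for horizontal cells, 5 and 4 for amacrine cells and 2 and 7 for ganglion cells. Camera's direction turned for cones without fresh-frozen replicate 1 (median 0.00623) or PFA-fixed replicate 4 (-0.0647), and for horizontal cells without fresh-frozen replicate 3 (-0.14). For amacrine cells it turned without fresh-frozen replicate 1 (-0.12) or 2 (0.00603) or PFA-fixed replicate 1 (-0.12) or 4 (-0.16).

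Cilium, synapse and splicing genes were higher relative to other genes. Of 29 cilium and outer segment genes, 24 rose and none fell, with a median of 0.64 (camera adjusted p = 1.40e-06; adjusted p = 0.163 with an estimated correlation). Adjusted over the list alone, 24 rose and 1 fell. TULP1, CEP290 and RPGR, each linked to inherited retinal degeneration, rose by 2.18, 1.43 and 1.83. Of 29 splicing and RNA processing genes, 26 rose and none fell, also when adjusted over the list alone, with a median of 0.66 (camera adjusted p = 1.00e-07; adjusted p = 0.163 with an estimated correlation). SNRNP70 rose by 1.93, PNISR by 1.56 and HNRNPU by 0.80 (0.15 with the rod list median, where its call ended). SON rose by 0.28, a call that ended with quantile normalization (0.15) and with centring on the mean of the rod list (0.03), and its change was -0.36 with the rod list median. Under that scaling the cilium and splicing medians were -0.0102 and 0.012, and both lists still passed (camera adjusted p = 3.65e-06 and 1.17e-05). Of 27 synapse genes, 13 rose and 2 fell, also over the list alone, with a median of 0.18 (camera adjusted p = 0.0251; adjusted p = 0.520 with an estimated correlation). The calcium channel gene CACNA1F rose by 1.57, UNC13B by 1.21, SYT1 by 0.77 and RIMS2 by 0.76. With the rod list median, SYT1 and RIMS2 differed by 0.12 and 0.11 and were not called. The call of the synapse list ended under quantile normalization (camera adjusted p = 0.147), with the minimum level of 3 log2 CPM (camera adjusted p = 0.0509) and with the rod list median (median -0.47, camera adjusted p = 0.124). Its median was -0.0759 with the rod list mean, 0.32 without fresh-frozen replicate 3 and 0.27 without fresh-frozen replicate 4.

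Of 77 cytosolic ribosomal protein genes, 54 fell and 8 rose, also over the list alone. Their median was -0.63 (camera adjusted p = 1.51e-06, and 0.520 with an estimated correlation). It was -0.89 and -1.28 with the rod list mean and median. RPL13 fell by 1.52 and RPL11 by 0.83. Many of these genes have pseudogenes that can share reads. The list took 1.31 ± 0.0748% of the fresh-frozen and 0.806 ± 0.0638% of the fixed library (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0381 over 4 shares). Of 66 mitochondrial ribosomal protein genes, 25 rose and 16 fell, with a median of 0.05 (camera adjusted p = 0.325), and MRPL30, MRPL51 and MRPS35 rose by 1.78, 1.47 and 1.34. This median was -0.20 with the rod list mean, -0.60 with the rod list median and 0.0059 to 0.066 without single libraries.

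Of 63 nuclear genes of the respiratory chain, 22 rose and 27 fell, also over the list alone, with a median of -0.13 and a mean of 0.05 (camera adjusted p = 0.793, downward, where fry pointed upward). NDUFA9 rose by 3.66, from 6.27 ± 0.05 to 9.93 ± 0.12 log2 CPM (SD, n = 4 each), and ATP5MJ, at the lowest value in 1 fresh-frozen library, by 2.80. The ATP synthase genes ATP5F1A and ATP5F1B fell by 0.86 and 0.77. Of 17 replication-dependent histone genes, 5 rose and 6 fell, also over the list alone, with a median of -0.37 (camera adjusted p = 0.827), and of -0.34 to -0.22 without single libraries. H2AC9, H1-5 and H2AC10 fell by 1.89, 1.85 and 0.64 and H2AC19 rose by 0.48 (-0.17 with the rod list median). These transcripts are near-identical, so their single values are uncertain.

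Of 23 immediate early response genes, 16 fell and 1 rose, also over the list alone, with a median of -1.37 (camera adjusted p = 0.000175; adjusted p = 0.182 with an estimated correlation). CCN2, a matricellular gene that fibroblasts express strongly, fell by 5.05, KLF2, an endothelial factor gene, by 4.37 and JUND by 1.85, while JUN differed by -0.01 as deposited and was called lower with the rod list median (-0.66). Of 21 hypoxia and glycolysis genes, 17 fell and 2 rose, also over the list alone. Their median was -0.46 (camera adjusted p = 0.00746, and 0.382 with an estimated correlation). It was -0.71 and -1.11 with the rod list mean and median. EGLN3 fell by 2.87 and ALDOC by 0.62, and CA9 rose by 1.21 (0.57 with the rod list median, where its call ended). Of 15 genes often used as references, 11 fell and 1 rose, also over the list alone. Their median was -0.36 (camera adjusted p = 0.0151, and 0.163 with an estimated correlation). It was -0.61 and -1.01 with the rod list mean and median. The actin gene ACTB fell by 1.79 and EEF1A1 by 1.36. GAPDH, a member of both lists, fell by 0.28 (limma adjusted p = 0.0148), a call that ended without PFA-fixed replicate 1 (-0.24) and with centring on the median (-0.20).

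Stress lists did not pass with camera. Fry called the heat shock, unfolded protein response and cytokine lists down (fry adjusted p = 0.000296, 0.000192 and 0.0116). Of 14 heat shock and protein folding genes, 8 fell and 2 rose, with a median of -0.31 (camera adjusted p = 0.233), and HSPB1, BAG3 and HSPA8 fell by 1.74, 1.44 and 0.36. Of 15 unfolded protein response genes, 9 fell and 4 rose, with a median of -0.39 (camera adjusted p = 0.233). ATF5 and HERPUD1 fell by 1.43 and 1.25, ATF4 rose by 0.43 (-0.22 with the rod list median) and HSP90B1 differed by 0.01 as deposited, and was called lower after quantile normalization (-0.19) and with the rod list mean (-0.24) and median (-0.64). Of 13 cytokine and interferon response genes, 9 fell and 3 rose, with a median of -0.74 (camera adjusted p = 0.174), and OAS2, IRF1 and MX1 fell by 2.33, 1.91 and 0.74. Of 3 lens genes, CRYGS rose by 1.89, CRYBB3 fell by 1.20 (-0.74 and not called after quantile normalization) and BFSP1 differed by -0.12 (-0.37 and -0.76 with the rod list mean and median, called in both). ALAS2, the only erythrocyte gene measured, differed by -0.26 (-0.52 to -0.071 without single libraries, and -0.91 with a call with the rod list median). Counts of these lists were the same when adjusted over the list alone.

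In all, camera called 14 of 27 lists with the preset correlation, 3 up and 11 down, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05. Of the 35 splits of the 8 libraries into 4 and 4, 10 called at least 14 lists, the real split included. Some of the other splits keep part of the difference between the preparations. The splits therefore cannot decide whether chance gives this number of called lists, and chance is not excluded for it. Fry, which asks only whether a list's own genes move one way, called 21 lists, 6 up and 15 down, and 27 for change in either direction. Beside the 14 lists of camera, it called the rod, bipolar cell and mitochondrial ribosomal protein lists up. It called the oligodendrocyte, heat shock, unfolded protein response and cytokine lists down.

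**Figure D3:**
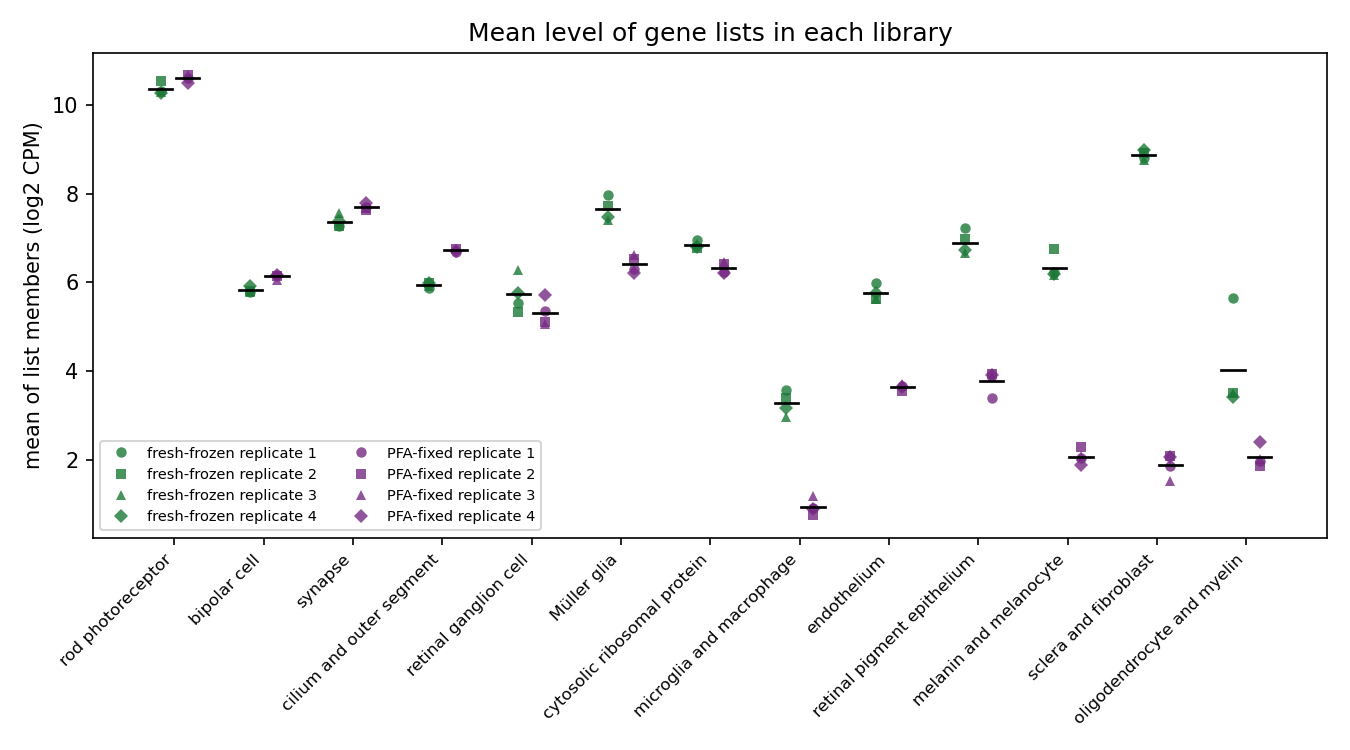
Mean level of the members of 13 gene lists (y axis, log2 CPM) in each of 4 fresh-frozen (green) and 4 PFA-fixed (purple) libraries, with a marker shape for each replicate number and group means as black bars. The sclera and fibroblast list separates the groups most, rods hardly differ, and fresh-frozen replicate 1 stands at 5.66 for the oligodendrocyte and myelin list.

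Composition of the libraries differed too. At least 1 CPM was reached by 12622 ± 26.9 genes in fresh-frozen and 12482 ± 28.5 in PFA-fixed libraries (SD, n = 4 each), a difference of -140.2 (exact permutation p = 0.0286, two-sided), in a table that holds only genes above 1 CPM in at least 4 libraries. The 10 most abundant genes took 5.97 ± 0.148% of the fresh-frozen and 9.45 ± 0.520% of the fixed library, and the 100 most abundant 18.9 ± 0.372% and 22.5 ± 0.355% (SD, n = 4 each; exact permutation p = 0.0286 and adjusted p = 0.0381 for each). RAPGEF5 alone took 1.07 ± 0.202% and 3.81 ± 0.181%, and ZNF507 took 0.146 ± 0.0509% and 1.06 ± 0.246%, both chosen after seeing the data. Whether reads of RAPGEF5, ZNF507 and SLC38A4 come from a repeat or another RNA within these genes was not tested. The rod list took 4.90 ± 0.305% and 5.16 ± 0.165% (exact permutation p = 0.257, adjusted p = 0.257).

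Libraries of one preparation were alike and the preparations stood apart. Across genes, Pearson's r had a median of 0.980 within fresh-frozen (0.977 to 0.987), 0.988 within PFA-fixed (0.984 to 0.990) and 0.850 between them (0.832 to 0.862), and Spearman's rho medians of 0.986, 0.993 and 0.876. The first principal component held 86.2% of the variance and separated the groups. Over genes with a mean of at least 3 log2 CPM the r between preparations was 0.789. The median SD between replicates was 0.146 in PFA-fixed and 0.159 in fresh-frozen retina, a difference of -0.0136 that did not pass (exact permutation p = 0.257 over 35 splits) and that became 0.00108 without fresh-frozen replicate 3. The change rose weakly with level across genes (Spearman's rho = 0.139), from a median of -0.20 in the lowest of 4 equal groups of genes by mean level to 0.11 in the highest. The slope of a library against the mean fresh-frozen level was 0.994 ± 0.0157 in fresh-frozen, each left out of its own mean, and 0.936 ± 0.0143 in PFA-fixed libraries (SD, n = 4 each). Fresh-frozen libraries are set against their own group there and fixed ones against the other group, so the comparison carries no p.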

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

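MOG, MAG, OLIG1, OLIG2 and GFAP were chosen after the high value of the myelin list had been seen, and no test rests on them. Of 328 groups of 4 values tested for a library far from the other 3, 20 had one, where chance gives about 16.4.

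The mean of the oligodendrocyte and myelin list was 5.66 log2 CPM in fresh-frozen replicate 1, against 3.43 to 3.52 in the other 3 fresh-frozen libraries, and CNP was 6.52 there, against 4.47 to 4.71. The list members MOG, MAG, OLIG1 and MBP exceeded the next fresh-frozen library by 2.62, 2.80, 4.80 and 3.41 there and the astrocyte gene GFAP by 4.07. ERMN and MAL exceeded it by only 0.72 and 0.13, and OLIG2 and SOX10 were not highest there (-0.0376 and -0.248). Optic nerve tissue in that library stays open and untested. No biological explanation was tested, and without this library the list median was -1.34 in place of -1.65.

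In the same library 7 genes stood at the lowest value of the table, against 1 to 2 in the other 3, and MX1 stood apart as high at 6.30 log2 CPM. In fresh-frozen replicate 2, the mean of the melanin list stood apart as high at 6.75 and that of the rod list at 10.53, as did PRPH2 at 11.98 and TULP1 at 8.65, while H2AC9 was low at 5.02. In fresh-frozen replicate 4, ATP5F1A was low at 8.74 and MRPL51 was high at 5.31. Among PFA-fixed libraries, replicate 2 was high for DCT at 2.27, MRPL33 at 7.03 and TULP1 at 11.03. PFA-fixed replicate 4 was low for RGR at 6.59, RPL13 at 5.64 and RIMS2 at 10.83 and high for BAG3 at 5.13. The mean of the pigment epithelium list was low in PFA-fixed replicate 1 at 3.41, and that of the bipolar list in replicate 3 at 6.05. All are in log2 CPM except the count of genes.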

How the results depend on the processing

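Log2(CPM + 1), library quality weights and both centrings on the rod list were added after seeing the data, the version on the list mean after the result of the version on the list median. Of 112 called genes among the 123 named, 90 were tested in all 18 alternatives, and 65 of these kept direction and call in all. The other 22 lay below the minimum mean of 3 log2 CPM, so that alternative has no value for them, and 17 of them kept direction and call in the rest. The microglia and macrophage list could not be tested with that minimum, where camera called 12 of 26 lists. Leaving out single libraries gave 8338 to 8649 called genes, 8265 to 8411 of them among the 8804, and 14 to 15 lists. The replicate block called 8799 genes, 8613 of them among the 8804, and 15 lists, with the rod list added. Whether equal numbers mark one dog stays open. Deviations of same-numbered libraries correlated between -0.0893 and 0.224, and 3 of 4 fixed but 1 of 4 fresh-frozen libraries correlated best with their own number. Not run were alternatives that need counts (thinning, other size factors, DESeq2, voom, no filter) and a smaller pseudocount, as the values are log2 with a prior. Also not run were corrections for length and GC content, relations to length, GC content and span, protein-coding genes alone, and leaving out mitochondrial and small structural RNA genes, of which none is measured. Fixed libraries were shallower, with 1 read worth 0.0649 to 0.0906 CPM against 0.0439 to 0.0462 in fresh-frozen ones, which limits changes near the lowest value.

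The test against 1.5-fold called 3343 genes, 1530 up and 1813 down, as it asks for a larger change. With a mean of at least 3 log2 CPM, 1000 genes fell at least 2-fold from 10153 tested, and the r between preparations was 0.789. Centring on the rod list mean left 2685 rising genes, 888 of them at least 2-fold. Centring on the rod list median gave 1138 rising and 8074 falling genes, 424 and 4180 of them at least 2-fold. Both lower the fixed libraries relative to the fresh-frozen ones. The mean change of the rod list was 0.25 as deposited, which centring on its mean removes. The median of its members' mean levels went from 10.25 to 10.96 log2 CPM, more than the median change of the members (0.22). Centring on the list median therefore overshot the rod genes, whose median change was then -0.43. Turns and lost calls under that centring can come from this overshoot. Camera with an estimated correlation called 0 lists, 8 at an unadjusted p under 0.05, and fry called 21. The difference in spread ran from -0.0317 to 0.00108 without single libraries, turning without fresh-frozen replicate 3.

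Directions turned as follows, and the cause was not tested. For lists, a turn is one of camera's direction, and the value in brackets is the median change, which need not change sign. Without single libraries, the ranges were -0.0598 to 0.0386 for SLC38A4, -0.0397 to 0.0109 for SLC45A2, -0.12 to 0.0899 for JUN, -0.20 to 0.11 for PDE6H, -0.0197 to 0.0309 for HSP90B1 and -0.21 to 0.00351 for BFSP1. List medians ran from -0.0647 to 0.21 for cones, -0.16 to 0.15 for amacrine cells and -0.25 to -0.14 for horizontal cells, where camera's direction turned. Quantile normalization gave SLC38A4 -0.52, GNB1 -0.21, HSP90B1 -0.19, PRPH2 -0.026 and ALAS2 0.0929, and turned camera's direction for the rod (-0.00716), cone (0.11) and amacrine (0.21) lists. Median centring gave PDE6H 0.028, SLC45A2 0.0691 and JUN 0.0727. Centring on the rod list mean gave SLC38A4 -0.25, HSP90B1 -0.24, GNB1 -0.14 and MRPL33 -0.0149, and turned camera's direction for the amacrine (-0.39) and histone (-0.62) lists, while the medians alone changed sign for cones (-0.13), mitochondrial ribosomal proteins (-0.20) and synapse genes (-0.0759). Centring on the rod list median gave SLC38A4 -0.65, HSP90B1 -0.64, GNB1 -0.53, MRPL33 -0.41, HSP90AA1 -0.39, PRPH2 -0.38, SON -0.36, ATF4 -0.22, PROX1 -0.18, H2AC19 -0.17, PAX6 -0.13, MAP1B -0.13 and TPM3 -0.0259, and turned camera's direction for the amacrine (-0.79) and histone (-1.02) lists, while the medians alone changed sign for cones (-0.53), bipolar cells (-0.25), mitochondrial ribosomal proteins (-0.60), synapse (-0.47) and cilium (-0.0102) genes. The rod list's own median change was -0.039 with its mean and -0.43 with its median, values that the centring sets. Without a turn, the calls of CNGB1 (0.20), CHAT (0.31), NEFM (0.047), CA9 (0.57), RIMS2 (0.11), SYT1 (0.12) and HNRNPU (0.15) ended with the rod list median, and KDR (-0.80), SLC45A2 (-0.66), BFSP1 (-0.76), PDE6H (-0.70), JUN (-0.66) and ALAS2 (-0.91) became calls. With the rod list mean, the calls of PRPH2 (0.015), PAX6 (0.26), CHAT (0.70), NEFM (0.44) and SON (0.030) ended, and KDR (-0.41), SLC45A2 (-0.26) and BFSP1 (-0.37) became calls. Quantile normalization ended ONECUT3 (-0.46), CRYBB3 (-0.74) and SON (0.15) and called KDR (-0.27). Median centring ended GNAT1 (-0.15), ONECUT3 (-0.77) and GAPDH (-0.20) and called HSP90AA1 (0.34) and MRPL33 (0.32), both also called with the replicate block, and log2(CPM + 1) ended GNAT1. The test against 1.5-fold ended the calls of 27 named genes. Library weights gave SLC38A4 -0.0101, SLC45A2 0.0141 and JUN 0.00566. The minimum of 3 log2 CPM turned camera's direction for the amacrine list (0.039), and fry pointed the other way from camera for the amacrine (-0.14) and respiratory chain (-0.13) lists.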

Other observations

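The gene families, and the tests on depth, recovery, genomic DNA and low values, were chosen after the results were seen. Of 17 families formed by symbol, 15 were large enough for camera, which called 9 with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. Collagen genes divided. Of 39, 23 fell and 10 rose (median -1.70, camera adjusted p = 0.00166; adjusted p = 0.141 with an estimated correlation), from COL1A1 at -9.27 to COL7A1, COL9A1 and COL22A1 at 2.48, 2.60 and 2.94. Of 10 laminin genes 7 fell and none rose (median -1.27, camera adjusted p = 0.00251; adjusted p = 0.141 with an estimated correlation), led by LAMC3 and LAMA2, and of 13 lysosomal cathepsin genes 10 fell and 1 rose (median -1.62, camera adjusted p = 0.00166; adjusted p = 0.141 with an estimated correlation). Of 36 proteasome genes, 25 fell and 5 rose (median -0.32, camera adjusted p = 0.00938; adjusted p = 0.141 with an estimated correlation).

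Nuclear and axonemal families went the other way. Of 18 lysine methyltransferase genes 12 rose and 1 fell (median 0.44, camera adjusted p = 0.00251; adjusted p = 0.141 with an estimated correlation), with KMT2D up by 1.54 and KMT2A by 1.11. Of 10 axonemal dynein genes 7 rose and none fell (median 0.59, camera adjusted p = 0.0106; adjusted p = 0.141 with an estimated correlation). Among 236 ZNF zinc finger genes 112 rose and 40 fell (median 0.21, camera adjusted p = 0.00307; adjusted p = 0.141 with an estimated correlation), but the median turned to -0.0468, with 66 up and 75 down, when libraries were centred on the mean of the rod list. With the rod list median, the medians of the zinc finger, methyltransferase and axonemal dynein families were -0.44, -0.21 and -0.0634, so their rises depend on the scaling. Zinc finger genes then numbered 23 up and 121 down, and methyltransferase genes 4 up and 7 down. Both calls ended (camera adjusted p = 0.0603 and 0.0561). Axonemal dynein genes numbered 4 up and 0 down, and that family was still called (camera adjusted p = 0.00322). The families named above as falling kept a negative median under quantile normalization, median centring and both rod centrings. ZNF507 rose by 3.01 to 13.40 log2 CPM.

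The count of 8804 differing genes was not matched by another split. Of the 35 splits of the 8 libraries, 1, the real one, gave as many, and the highest other gave 0 genes with limma. This is the smallest share that 35 splits allow, so chance is made unlikely but is not excluded. The other splits mix both preparations, whose difference then widens the spread within their groups, so few calls were to be foreseen there. At an unadjusted p under 0.05, the real split gave 9154 genes and the highest other 1160. For the number of called lists, the splits cannot decide, because some of the others keep part of the difference between the preparations. Chance is not excluded for it. Of the 35 splits, 10 gave at least the 14 lists of the real split, and the highest other gave 17.

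Fibrous and pigment lists fell by medians of -7.02 and -5.31, and the pigment epithelium list by -3.50. Lower depth of fixed libraries is argued against as the whole cause, because the sclera median lay at percentile 0 among 10000 lists matched on fresh-frozen level, as did the medians of the melanin and pigment epithelium lists. More tissue outside the neural retina in the fresh-frozen libraries stays open, and no test here decides on it. Genes of such tissue were high there (COL1A1 at 11.80, RPE65 at 9.58 and PMEL at 8.65 log2 CPM), while RGR, which Müller cells also express, fell by 0.48 to 6.84, and SLC45A2 was at 6.26 in fixed ones. Outer tissue whose RNA was not recovered after fixation cannot be told apart from its absence, since 0 libraries separate fixation from the proteinase K extraction, and a difference between right and left eyes, the one biological difference in the labels, stays open and untested.

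The 214 genes that rose at least 4-fold had a median of 2.41 log2 CPM in fresh-frozen and 4.99 in fixed libraries, with no overlap between groups in any of them. They were chosen in these same libraries for a called rise of that size, so the lack of overlap adds no support. Of 279 genes chosen for a 4-fold rise between replicates 1 and 2 of each group, 98.2% rose at least 2-fold between replicates 3 and 4. So did 94.6% of the 93 with a mean under 3 log2 CPM in the fixed libraries used to choose. Most of these rises therefore repeated in the other libraries. The filter of the table, however, holds a gene under 1 CPM in all 4 fresh-frozen libraries only if it exceeds 1 CPM in all 4 fixed ones. Part of the repeated rise of low genes is set by this filter, so the test cannot decide on noise of low values for them. Genomic DNA that adds reads evenly to all genes is argued against as the cause of a median gain of 25.9 CPM in the rising genes. Under 1 CPM in all 4 fixed libraries were 163 genes (53 in all 4 fresh-frozen). By the filter of the table, each of the 163 exceeded 1 CPM in all 4 fresh-frozen libraries. A smaller amount of DNA, or DNA reads at repeated sequence, is not excluded by this. Spill-over from an abundant neighbouring gene is argued against as a common cause over the 172 rising genes with a measured neighbour. The median level of their more abundant neighbour, 5.61 log2 CPM, lay at percentile 58.7 among 10000 sets matched on fixed level. Neighbours were taken by the order of genes alone, without distance, overlap or strand. The test therefore does not cover single genes or a subset with close or overlapping neighbours. Nor does it cover rising genes without a measured neighbour, or neighbours that the table does not hold. Unspliced RNA, sequence shared with repeats or other transcripts, and the extraction kits stay open and untested, as does a difference between right and left eyes.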
